A study of Homo sapiens with 2 samples.

How the data were processed

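Messenger RNA levels of cells labelled U937 with a miR-194-5p vector and with an empty vector were measured on 2 dye-swapped 2-colour Agilent arrays. The series title calls the control a scramble, while the sample labels call it an empty vector; the labels' term is used. Per the file headers, each array was read with Agilent Feature Extraction, of which the submitters' processing notes give version 10.5.1.1. The deposited files hold, per the file headers, median intensity values of each spot and of its background in the green and red channels, with no normalization. They also hold processed intensity values, which per the file headers were background-subtracted, spatially detrended and dye-normalized by linear and lowess factors. The log10 ratio of red over green and its p-value from the software's error model were computed from these by the scanner software, per the file headers. The deposited series matrix holds a single value per probe and array on a natural log scale, made by the authors in a way not given in the sources used here. Its scale and direction were found from the scanner values: over 5230 and 5606 bright spots its slope on the scanner's log2 ratio of red over green was 0.692 on replicate 1 and -0.654 on replicate 2, near the natural log of 2 (0.693). It is thus already turned to miR-194-5p over empty vector on both arrays. Its medians were 0.0107 and 0.000988, and how it was centred stays unknown.

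Each array had 45015 spots, of which 1639 were controls, 2 were flagged as non-uniform outliers and 0 were saturated. Both arrays were on 1 slide and in 1 scan, so slide and scan cannot be separated as batches. The median signals were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0 and outlier spots left out. The design fixed before the data were examined named mean signals; the median signals were used in their place. Ratios were turned by the dyes in the labels. Spots of a probe were averaged, and probes with at least 1 channel well above background on both arrays were kept, which left 21157 of 41000. The mean log2 ratio was tested two-sided with lmFit and eBayes, with 1 residual degree of freedom per probe, moderated to 8.04, and Benjamini-Hochberg adjustment. A dye term would have left no residual degree of freedom. The inputs were read with jsonlite 2.0.0 and the data.table package (1.17.8), and Python 3.11.15 with matplotlib 3.10.9 drew the plots.

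Where a probe past the threshold was not well above background on either array in 1 group, the change is a bound. It sets the brighter group's mean against, for each array, the higher of the lowest signal among probes well above background and the dim probe's own signal, after loess and Aquantile. Such a bound applied to 290 of the probes past the threshold.

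Probes were named by matching their accession, without versions, to the RefSeq table of GRCh38.p14. This gave a symbol to 23958 of 41000 probes (58.4%) and none to 17042. The array design was annotated on another assembly, hg18, so no coordinates are given. A gene is represented by its brightest probe. Of 3283 genes with several tested probes, 0 had probes past the threshold in both directions.

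The named genes are the 12 with the highest and the 12 with the lowest mean log2 ratio among named genes past the threshold with 1 sign on both arrays, provisional names left out, BCLAF1, the host genes of miR-194, and up to 4 members of each list, those past the threshold first. GFI1, CEBPA, LYZ and CSF1R and the genes at the ends of runs were named after their values were seen. The 21 gene lists were fixed before the data were examined: reported miR-194-5p targets, monocyte and macrophage markers, myeloid progenitor and primary granule genes, cell cycle, apoptosis, type I interferon response, NF-kB and inflammatory genes, MHC class I and class II, microRNA machinery, cholesterol synthesis, unfolded protein and amino acid response, hypoxia and glycolysis, heat shock, oxidative phosphorylation, cytosolic ribosomal proteins, adhesion and matrix, chromatin modifiers, and lymphoid, erythroid and epithelial or fibroblast markers. Of their 536 symbols, 521 were on the array and 429 were measured. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and by the median against 10000 random lists matched on brightness. With the correlation estimated, camera rests on 1 residual degree of freedom, and its smallest unadjusted p for any list was 0.265. That setting could hardly call a list, so its adjusted p does not count against a list.

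The steps were tested on simulated arrays with the brightness, dye curve and spread of the real ones. Of 100 probes changed 4-fold 41% were called, of 100 changed 2-fold 1% were called, and 2 of 20957 unchanged probes were called. With so few probes changed, the adjusted threshold was stricter than in the real data, where 2016 probes passed. The 41% and 1% are therefore not the sensitivity of the real fit. In the simulated list test 1 of 19 lists was shifted and 1 was called. Its genes were drawn independently and tested at the preset correlation. It therefore does not show how camera behaves where genes shift together, as in the real data. For neighbouring genes, a run of 60 genes shifted by 1 on the log2 scale in shuffled data gave a running median of 0.893. The alternatives were processed signals, no background subtraction, an offset of 16, median centring, other filters, scaling between arrays, saturated spots left out, the series matrix, other variance models and thresholds, each replicate left out, and the neighbours' median subtracted. A test of miR-194-5p seed sites was planned and was not run, because no transcript or probe sequences were used here.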

Results

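Total RNA of cells labelled U937, an established human line of leukaemic monocyte lymphoma, was compared between cells carrying a vector for the microRNA miR-194-5p and cells carrying an empty vector. A microRNA is a short RNA that pairs with messenger RNAs and lowers their stability or translation. Both cultures grew in medium with 10% serum and 0.5 µg/µl G418, a drug that selects cells holding the vector. The 2 RNAs were hybridised together on each of 2 Agilent arrays, which the labels call biological replicates, and the dyes were exchanged between the arrays. The miR-194-5p RNA carried Cy5 on replicate 1 and Cy3 on replicate 2. Of 41000 probes, 21095 and 18832 were well above background in the miR-194-5p channel of replicates 1 and 2, and 17848 and 23831 in the empty vector channel. The slope of observed on expected log ratios of the spike-in controls was 0.926 on replicate 1 and 0.917 on replicate 2. The identity of the 2 cultures rests on the labels and was not tested. The labels do not say whether the replicates came from separately transfected cells, so the p-values measure the spread between these 2 arrays, whose number limits the precision.

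The comparison asks which messenger RNAs differ between the cells with the miR-194-5p vector and with the empty vector. The highest ratios belonged to BEX2 and BEX1, neighbouring members of a family of small brain-expressed proteins. BEX2 was 324-fold higher in the miR-194-5p cells, with a log2 ratio of 8.34 ± 0.34 (limma standard error, n = 2 arrays), and BEX1 was 232-fold higher, at 7.86 ± 0.38. MPO, the myeloperoxidase of primary granules, was 42.4-fold higher at 5.41 ± 0.35. On the other side, PIR, which encodes the nuclear protein pirin, was at least 106-fold lower, and the neuropeptide gene GAL was lower with a log2 ratio of -6.49 ± 0.32. The calprotectin subunit gene S100A8 was at least 36.0-fold lower.

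In limma, 2016 of 21157 tested probes (9.53%) passed a Benjamini-Hochberg adjusted p of 0.05, 938 higher and 1078 lower in the miR-194-5p cells. By 1 probe per gene, 1259 of 10265 named genes passed, 543 higher and 716 lower. The median change of the probes that passed was 2.91-fold, and the smallest log2 ratio among them was 1.12 in size. With median centring in place of loess the count fell to 67 probes, 20 higher and 47 lower, and the share of higher calls moved from 46.5% to 29.9%.

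The ratios of the 2 arrays, both turned to miR-194-5p over empty vector, had a Pearson r of 0.641 and a Spearman rho of 0.512 across the tested probes, which are not independent replicates. On both arrays 880 probes were at least 2-fold higher and 1003 at least 2-fold lower. At least 2-fold ratios with opposite signs were found for 76 probes, a contrast chosen before the data were examined. Median centring turned the contrast round, with 830 probes at least 2-fold in the same direction, 3106 in opposite directions and a Pearson r of 0.328. At 16-fold, 10 probes were higher and 24 lower on both arrays, and 0 had opposite signs. With 1 array's sign turned around, limma called 0 probes, and 69 had an unadjusted p under 0.05 against 5499 in the labelled orientation. Turning 1 sign moves the differences shared by the arrays into the residual spread. Few calls were thus bound to follow, and these counts give no rate of false calls.

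**Figure D1:**
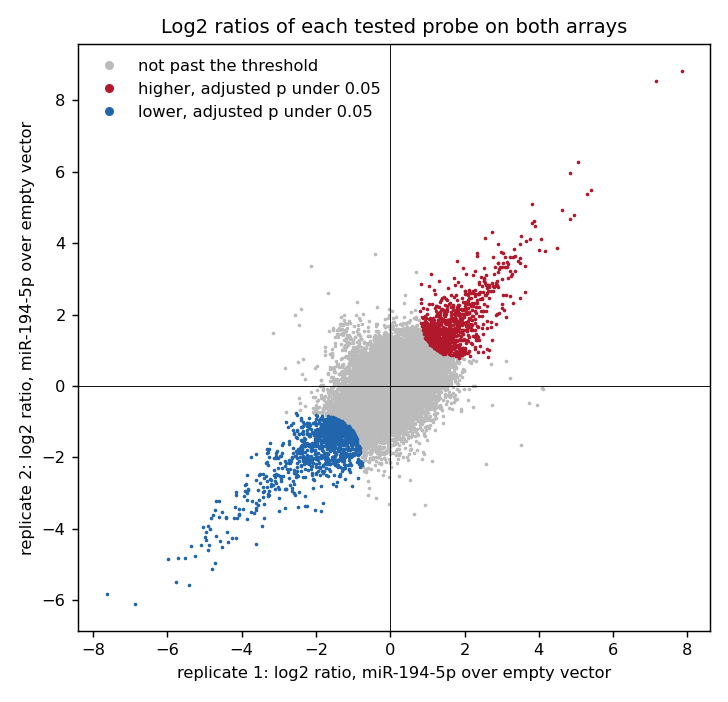
Each point is 1 of 21157 tested probes, with its log2 ratio of miR-194-5p over empty vector on replicate 1 (horizontal) and on replicate 2 (vertical). The 938 probes past the threshold as higher lie in the upper right and the 1078 lower ones in the lower left, and the Pearson r over the probes is 0.641.

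After BEX2 and BEX1, the 12 genes with the largest increases included TCEAL8, which was not well above background in the empty vector cells and was at least 50.9-fold higher. CALHM6 was 43.5-fold higher, and IL18RAP, an accessory chain of the interleukin-18 receptor, was 27.4-fold higher. NR2F2, a nuclear receptor that is on the list of reported miR-194-5p targets, was 22.1-fold higher by its brightest probe, with a log2 ratio of 4.47 ± 0.37 and 2.91 by its other probe. HDGFL3 was at least 18.9-fold higher, and the guanylate-binding protein gene GBP5 was 18.2-fold higher. The glutamate transporter SLC1A3 was 15.7-fold higher by its brightest probe, but its other probe, at a log2 ratio of 0.89, did not pass (adjusted p = 0.0986). MEF2C, a transcription factor of muscle and blood cells, was 15.4-fold higher, and the integrin subunit ITGA7 was 14.6-fold higher. Adjusted p of these 12 genes lay between 0.000150 for BEX2 and 0.000607 for NR2F2.

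Among the 12 genes with the largest decreases, TBXA2R, the thromboxane A2 receptor, was 42.8-fold lower by its brightest probe, and its other probe had a log2 ratio of -1.31. CTBP2, a transcriptional co-repressor, was 31.4-fold lower by its brightest probe and at least 2.61-fold lower by its other probe, which was not well above background in the miR-194-5p cells. IFI30, a thiol reductase of lysosomes, was 32.2-fold lower, MLC1 was 27.4-fold lower and the small GTPase RAB31 was 25.4-fold lower. In the miR-194-5p cells VCX3A, VCX, TMEM14A and PCOLCE2 were not well above background, which gives decreases of at least 38.3-fold, 30.3-fold, 28.6-fold and 26.9-fold. VCX3A and VCX are near-identical copies that a probe may not part, so their separate values are uncertain. Adjusted p of the 12 genes lay between 0.000217 for GAL and 0.000292 for VCX. All 24 genes kept their direction and passed under each alternative of the processing that tested them.

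**Figure D2:**
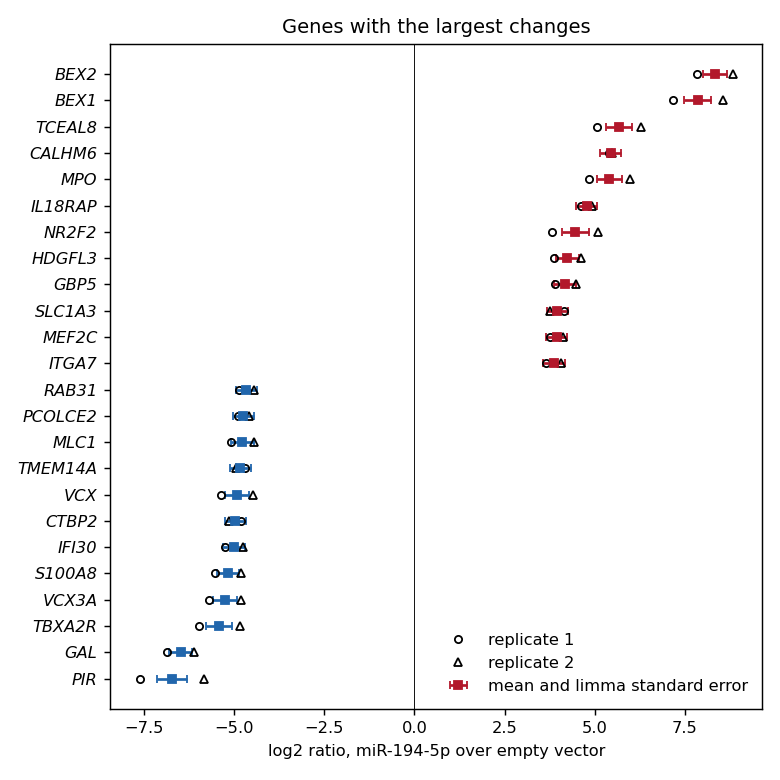
The 12 highest and 12 lowest genes past the threshold, by the brightest probe of each gene, on a log2 scale of miR-194-5p over empty vector. Squares with bars give the mean and its limma standard error, and open circles and triangles give replicates 1 and 2. BEX2 at 8.34 and PIR at -6.73 mark the ends. The values of PIR, VCX3A, VCX, S100A8, TMEM14A, PCOLCE2, TCEAL8 and HDGFL3 are bounds, since 1 group was not well above background on either array.

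BCLAF1, which encodes a BCL2-associated transcription factor and is known as a miR-194-5p target, did not pass. Its brightest probe had a log2 ratio of 0.37 ± 0.29 (adjusted p = 0.487), with 0.36 on replicate 1 and 0.38 on replicate 2. Its other probes went opposite ways, at -0.91 ± 0.31 (adjusted p = 0.112) and 0.91 ± 0.30 (adjusted p = 0.103). IARS2, a gene whose intron holds a miR-194 precursor, had a log2 ratio of -0.49 ± 0.33 (adjusted p = 0.407). Of 20 measured genes on the list of reported miR-194-5p targets, NR2F2 rose, 1 fell and 18 did not pass, with the same counts adjusted over the list alone. MAP4K4 and AKT2, with log2 ratios of -1.01 and -0.89 by their brightest probes, did not pass, and the other MAP4K4 probes went both ways (-0.15, 0.51 and 0.45). The list had a median log2 ratio of -0.33 and a mean of -0.04, and camera found no shift (adjusted p = 0.549). No probe on the arrays carried the name of miR-194, so the microRNA itself was not measured.

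Monocyte and macrophage markers were the only list of 19 tested that camera called, as lower in the miR-194-5p cells (adjusted p = 0.0367 at the preset correlation, adjusted p = 0.805 with an estimated correlation). The estimated setting rests on 1 residual degree of freedom and could hardly call any list. Of 21 measured markers 6 fell, 1 rose and 14 did not pass; adjusted over the list alone, 8 fell and 2 rose. Besides S100A8, its partner S100A9 fell at least 4.18-fold. NCF1, a subunit of the phagocyte oxidase, had a log2 ratio of -3.56 ± 0.36, and the lysozyme gene LYZ had -1.34 ± 0.29. CSF1R, the receptor of macrophage colony-stimulating factor, rose to 1.48 ± 0.33. The list's median was -0.61 on replicate 1 and -0.17 on replicate 2. At the preset correlation the call was lost with the scanner software's processed signals and with the filter on both channels.

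Myeloid progenitor and primary granule genes moved in both directions. Of 17 measured, MPO rose and 5 fell, and 11 did not pass; adjusted over the list alone, 1 rose and 7 fell. The neutrophil proteases ELANE and PRTN3 had log2 ratios of -2.99 ± 0.34 and -2.87 ± 0.42, the granule proteoglycan SRGN had -3.69 ± 0.30, and the transcription factors GFI1 and CEBPA had -1.52 and -1.26. Camera did not call the list (adjusted p = 0.222).

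Of 29 measured genes of the type I interferon response, 9 fell, 3 rose and 17 did not pass; adjusted over the list alone, 11 fell and 4 rose. IFIT2 and IFIT1 fell to log2 ratios of -2.71 ± 0.30 and -2.06 ± 0.29, while TRIM22 rose to 1.95 ± 0.32 and XAF1, not well above background in the empty vector cells, rose at least 3.74-fold. Camera did not call the list (adjusted p = 0.151). Of 18 NF-kB and inflammatory genes, 4 fell, 2 rose and 12 did not pass; adjusted over the list alone, 4 fell and 3 rose. The chemokine CCL2 was 16.7-fold lower, TNF had a log2 ratio of -2.18 and the adhesion receptor ICAM1 -1.48, while the chemokine CXCL2 rose to 1.70. Camera gave an adjusted p of 0.259. With the filter on both channels both of these lists were called lower at the preset correlation; in the main processing both had an adjusted p = 0.805 with an estimated correlation.

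Adhesion and matrix genes had 4 that fell, 2 that rose and 13 that did not pass among 19 measured (7 and 3 adjusted over the list alone). The laminin receptor subunit ITGA6 fell at least 24.8-fold, PLAU, the urokinase activator of plasminogen, was 11.4-fold lower, PECAM1 had a log2 ratio of -2.25 and TIMP1 -2.26. Of 60 cytosolic ribosomal protein genes 4 fell, 0 rose and 56 did not pass, with the same counts adjusted over the list alone. Among them were RPL13A (-1.57), RPS27 (-1.41) and RPL28 (-1.20). Camera did not call either list (adjusted p = 0.0888 at the preset correlation, adjusted p = 0.805 with an estimated correlation). At the preset correlation both were called lower with median centring and without the filter on dim probes, and the ribosomal list also with the filter on both channels and with the neighbours' median subtracted. The median of the ribosomal list against random lists gave an adjusted p of 0.0456, a test that leaves out any correlation between its genes. Camera's estimate of that correlation, 0.481, rests on 1 residual degree of freedom. It reflects only how many of the genes were higher on 1 array than on the other, and does not measure expression together. The list's median was -0.10 on replicate 1 and -0.58 on replicate 2.

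Of 33 apoptosis genes 4 rose, 1 fell and 28 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.185). BCL2 and BIRC3, which restrain cell death, rose to log2 ratios of 2.66 ± 0.32 and 2.09 ± 0.29, as did the initiator caspase CASP9 (1.55 ± 0.29), while BCL2L11, which promotes cell death, fell to -1.66 ± 0.29. Of 21 cholesterol synthesis genes HMGCS1, IDI1 and FDFT1 rose (1.30, 1.25 and 1.22), CYP51A1 fell (-1.54) and 17 did not pass (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.151). Without the filter on dim probes this list was called higher at the preset correlation; in the main processing it had an adjusted p = 0.805 with an estimated correlation. Of 23 hypoxia and glycolysis genes PDK1 and VEGFA fell (-4.01 and -1.79) and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.151).

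The remaining lists were not called by camera. Oxidative phosphorylation had SDHD higher (1.30) and 26 not past among 27 (0 adjusted over the list alone; adjusted p = 0.193), and the unfolded protein and amino acid response had PSPH and MTHFD2 higher (1.82 and 1.19) and 21 not past among 23 (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.364). For heat shock genes HSPH1 and HSP90AA1 rose (1.65 and 1.18), BAG3 fell at least 2.86-fold and 11 of 14 did not pass (4 rose and 3 fell adjusted over the list alone; adjusted p = 0.611). Of 39 cell cycle genes TYMS and BIRC5 rose (1.27 and 1.32), 3 fell, among them CCNE1 (-2.20) and E2F1 (-1.32), and 34 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.971); the median was 0.04, the mean -0.06 and camera's direction up. Of 25 chromatin modifiers HDAC4 rose at least 5.90-fold, SETDB1 and ASXL1 fell (-1.38 and -1.20) and 22 did not pass (2 and 2 adjusted over the list alone; adjusted p = 0.512). In the microRNA machinery 0 of 13 genes passed (1 rose and 1 fell adjusted over the list alone; adjusted p = 0.512), with TNRC6A at -1.05 and TNRC6B 2.14-fold higher by its brightest probe and at -0.22, 0.63 and 0.05 by the others, none past the threshold. PSMB9 rose (1.47) among 16 MHC class I and peptide loading genes, the same 1 adjusted over the list alone, and the list's median of -0.29 and mean of -0.02 were below 0 where camera's direction was up (adjusted p = 0.971). Of 6 MHC class II genes 0 passed, also adjusted over the list alone (adjusted p = 0.512). CD74, not well above background in the empty vector cells, had a log2 ratio of 0.50 and did not pass, so no least change is given. Its values were 0.28 on replicate 1 and 0.71 on replicate 2.

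Markers of other cell types were mostly not measured. Among 5 measured epithelial and fibroblast markers VIM, which monocytes also express, rose to 1.89 ± 0.30, the same 1 adjusted over the list alone (camera adjusted p = 0.512). Of 4 lymphoid markers 1 fell and 3 did not pass; adjusted over the list alone CD79A (0.98) rose as well. The erythroid and megakaryocyte markers EPOR (-0.36) and TFRC (-0.28) did not pass, also adjusted over the list alone. The last 2 lists had under 5 measured genes and were not tested as lists; the median of the lymphoid list was 0.29 and its mean -0.34.

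Several of these genes had probes that disagreed, and the values above are those of the brightest probe. The other probes of BCL2L11 had log2 ratios of -0.49 and -0.55, and those of CEBPA -1.39 and 0.34. HDAC4 was at least 4.25-fold higher by a further probe. By another it had a log2 ratio of 1.05 and did not pass (limma adjusted p = 0.0611). Neither probe was well above background in the empty vector cells, and the dimmest HDAC4 probe had 0.25. VEGFA had -1.03, -1.05 and -0.50, and HSP90AA1 had 0.67, 0.15 and 1.26. A further probe did not pass for CASP9 (1.02), CXCL2 (0.73), CYP51A1 (-0.73), HMGCS1 (0.64), PSPH (0.40), ASXL1 (-0.71), SETDB1 (-0.98) and RPL28 (-0.72).

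**Figure D3:**
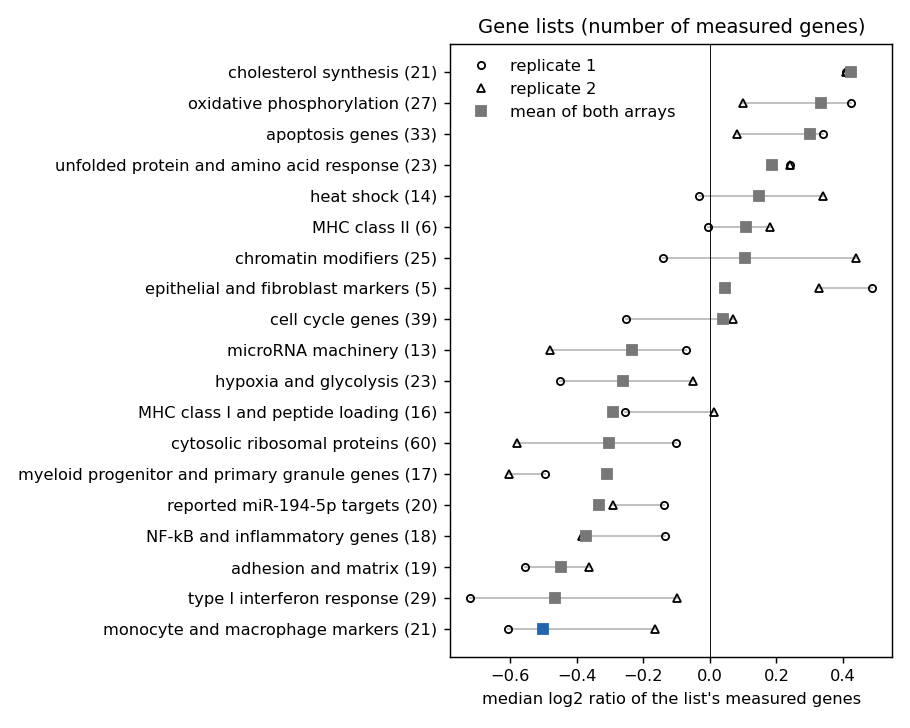
Median log2 ratio of miR-194-5p over empty vector for each list with at least 5 measured genes, as the median of the genes' means (squares) and of replicates 1 (circles) and 2 (triangles). The blue square marks the list called by camera, monocyte and macrophage markers with a median of -0.50; cholesterol synthesis has the highest median, 0.42.

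Neighbouring genes moved together in long runs, a property looked at after the values had been seen. Ordered as in the GRCh38.p14 annotation, 10260 genes gave running medians over 41 genes of up to 1.16 in size, against a highest value of 0.757 in 1000 shuffles of the gene order. Genes at the centre of windows past the 95th percentile of the shuffles formed 51 runs with 1091 genes (10.6% of those placed). Of the 51 runs 23 held at least 10 genes, and the shortest held 1. In the runs lay 266 of the 1256 placed genes past the threshold (21.2%). The runs were found from the same ratios, so some excess of such genes is built in. Genes near chromosome ends have no complete window of 41 genes and could not enter a run. VCX3A and VCX were left out in this way, although the medians of their neighbours were -1.09 and -1.02. From KCNK5 to CENPQ, a run that holds VEGFA, 53 of 56 genes were lower, with a median of -1.08. From NANP to PPDPF, a run that holds ASXL1 and E2F1, 179 of 187 genes were lower, and from COX7A2 to MYB, which holds CALHM6, 113 of 121 were higher. BEX1, BEX2 and TCEAL8 lay in a run from TRMT2B to PABIR2 with 62 of 71 genes higher and a median of 0.79. PIR lay in a run of 37 genes from HCCS to POLA1, of which 35 were lower, PDK1 and ITGA6 between STK39 and RBM45, TIMP1 between RP2 and SPIN2B, BCL2L11 between LIMS3 and VMA22, RPL13A between PPFIA3 and IRF3, and HMGCS1 between TTC33 and PAIP1. With the median of the 40 neighbours subtracted, VEGFA, SETDB1, ASXL1, BCL2L11, TYMS, E2F1, BIRC5, MTHFD2, RPL13A, RPS27, RPL28 and HMGCS1 no longer passed, TNRC6B passed (limma adjusted p = 0.0307), and 979 of 1539 named probes that passed still did.

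**Figure D4:**
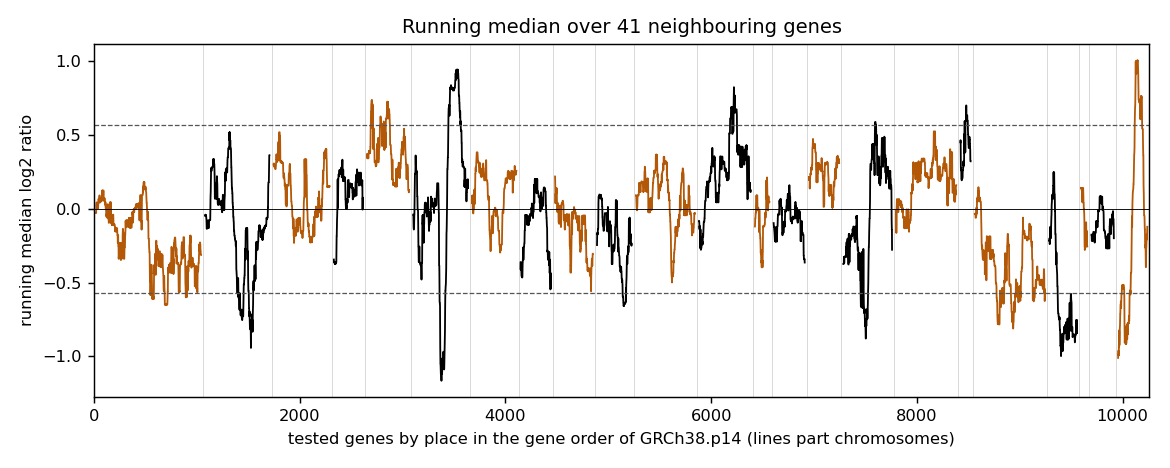
Running median of the log2 ratio of miR-194-5p over empty vector (vertical) over 41 neighbouring tested genes, along the gene order (horizontal), with colours alternating between chromosomes. Dashed lines give the 95th percentile of the largest running median in 1000 shuffles, 0.571 in size, and the curve reaches -1.16 between KCNK5 and CENPQ.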

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

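The subtraction of the neighbours' median was chosen after the results were seen; the other alternatives were chosen before the data were examined. The 24 genes with the largest changes kept direction and call in each of the 227 values that could be had. Of 104 named genes, the call was lost for 44 under median centring, 22 with the series matrix, 19 without the filter on dim probes, 17 with processed signals, 14 with the neighbours' median subtracted and 5 at offset 16, and for 8 of 75 with both channels above background. Median centring, which leaves the brightness-dependent dye trend in, called 67 probes, with 830 changed 2-fold on both arrays against 3106 with opposite signs, r = 0.328 and 3 lists. Without the filter on dim probes 831 of 40997 probes and 4 lists were called (r = 0.532), with both channels above background 1124 of 16493 probes and 3 lists (r = 0.622), and the authors' series matrix gave 985 calls (r = 0.599). Processed signals gave 1983 calls, of which 1323 were shared with the 2016 and with 1001 higher and 982 lower against 938 and 1078, 3666 probes changed 2-fold, 0 lists and r = 0.676, and the scanner's error model 6218 calls. The remaining counts of calls lay between 1603 and 2695. The correlation was 0.620 without background subtraction, 0.623 at offset 16 and 0.608 with the neighbours' median subtracted, which called the monocyte markers and the ribosomal proteins, 2 lists. A correlation estimated per list left 0 lists, an outcome all but fixed by its 1 residual degree of freedom. Random lists called 1, the ribosomal proteins in place of the monocyte markers. At 1.5-fold 4430 probes changed on both arrays. Without replicate 1 or 2 there is no test, and 3945 to 3958 probes changed 2-fold on the remaining array. For the differences other than that of the estimated correlation, the cause was not tested.

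BCLAF1 stayed between 0.12 and 0.41 without passing, and turned to -0.15 with the neighbours' median subtracted, as MUC1 (0.071), XPO5 (0.17) and EPOR (0.032) turned, none of them past the threshold. Camera's direction then turned for MHC class I (median -0.48) and microRNA machinery (median 0.00392). It also turned for reported targets under median centring (median -0.37), and for cell cycle genes under median centring (0.00604), with both channels above background (0.017) and with scaling (0.015), none called. No paired analysis was possible because each array already holds both RNAs and there is 1 group of ratios. Leaving out saturated spots moved nothing, since 0 were saturated. Seed sites, and the list test without a replicate, were not run. Signal over background limits the dim genes, for which 290 calls rest on a bound.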

Other observations

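The tests of dye bias, tandem families and reported targets, and the gene families, were chosen after the results were seen. The predictions for gene length and for the BCLAF1 probes were written before those tests were run. Both concern patterns found in the results, and neither test was in the design fixed before the data were examined. The dye test replaced a first version, which gave the 5 of 51 runs below. A test of segment dosage, whose bound was met, was dropped, because the share it rested on would be high under any real difference over a region. The gene families were picked for their calls, so no test of them is given. Of 10 measured cathepsins, proteases of lysosomes, 6 fell and 0 rose: CTSV had a log2 ratio of -2.89 ± 0.30, CTSA -2.09 ± 0.31, CTSD -1.75 ± 0.36 and CTSZ -1.64 ± 0.42, and CTSL and CTSK were at least 4.01-fold and at least 2.33-fold lower. Of 10 caspases 4 rose, CASP1 at 2.59 ± 0.33, CASP4 at 1.45 ± 0.29, CASP5 at 1.31 ± 0.30 and CASP9, and 0 fell. CASP1, CASP4 and CASP5, which act in inflammation, are neighbouring genes.

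Of 10 metallothioneins, small metal-binding proteins with near-identical copies whose separate values are uncertain, 4 rose, MT2A the most at 2.30 ± 0.30, and MT3 fell to -1.84 ± 0.30. HOXB3 (at least 6.75-fold), HOXA7 (1.74 ± 0.32) and HOXA4 (1.37 ± 0.31) rose among 9 HOX genes, DOCK8 (2.28 ± 0.29), DOCK11 (1.89 ± 0.33) and DOCK10 (1.37 ± 0.30) among 9 DOCK genes, and SEPTIN11, SEPTIN9 and SEPTIN6 among 7 septins, where SEPTIN10 fell at least 4.39-fold. Other probes of DOCK8 (1.60-fold, with 1 group not well above background), DOCK11 (0.61), SEPTIN9 (0.49) and SEPTIN6 (0.80) did not pass.

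The runs of neighbouring genes argue against dye bias, since the running medians of the 2 dye-swapped arrays correlated with r = 0.783; 5 of 51 runs had medians of opposite sign on the arrays, the longest of 3 genes. Tandem gene families and gene length do not account for the whole pattern. Genes 50 places apart still correlated (Spearman rho 0.156, against at most 0.0327 in shuffles). The largest running median was 1.17 after the trend on gene length was removed, against at most 0.664 in shuffles. Both values are taken over all genes, and the longest or strongest runs could give them alone. For the shorter runs they therefore decide nothing about tandem families or gene length. In runs found on replicate 1 alone, 774 of 961 genes (80.5%) lay on the run's side on replicate 2, against 73.7% of genes outside these runs with the nearest values on replicate 1, which does not part one cause from another. A hypothesis left untested is that the 2 cultures differ in the dosage of chromosome segments, so that part of the changes may belong to the lines that grew out and not to the microRNA. DNA was not measured, and regulation over whole segments or an effect of the vector would give the same values.

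The disagreement of the BCLAF1 probes was larger than is ordinary: their range of 1.82 lay at the 97.7th percentile of 530 genes with 3 tested probes. Transcript forms or a probe that pairs elsewhere may account for it, and neither was tested, so these arrays leave the direction of BCLAF1 open.

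Whether the reported miR-194-5p targets were lower as a set stays open. Their median of -0.33 lay at the 3.28th percentile of 10000 brightness-matched random lists (adjusted p = 0.143), at 28.6 on replicate 1 and 9.7 on replicate 2, camera's unadjusted p was 0.462 and NR2F2 rose 22.1-fold. The tables do not decide between a small shift and chance, and seed sites, which would bear on it, were not tested.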
